A study of Mus musculus with 2 samples.

How the data were processed

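RNA sequencing was available for 2 libraries of mouse bone marrow cells sorted as CD150-positive, Flt3-negative LSK cells, 1 from Satb1-Tomato-negative and 1 from Satb1-Tomato-positive cells. Total RNA was extracted with the miRNeasy kit and libraries were made with the Clontech SMARTer Stranded RNA-Seq kit, per the labels' protocols. The labels do not say how many animals each library pooled.

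The deposited values are FPKM, fragment numbers scaled by transcript length and by the total of mapped fragments, 1 value per gene symbol, per the file headers. The submitters' processing notes name TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cufflinks 2.2.1 with the mouse build mm10; the order, roles and settings of these tools, the gene annotation and the strand setting of counting are not given in the sources used here. FPKM from Cufflinks assigns fragments to isoforms and genes by a model, so genes that overlap or resemble other genes can gain or lose fragments in one library. Without strand in the counting, reads from a gene and an antisense partner cannot be told apart. Genes shorter than a sequenced fragment, such as small RNA genes, receive FPKM values that are unstable. Each file held 23235 rows. In 25 rows the symbol had been turned into a spreadsheet date or its serial number; these rows held 0.161% of the summed FPKM in the SATB1-negative and 0.172% in the SATB1-positive library and were left out. No symbol was repeated among the 23210 genes used, and 11873 had at least 1 FPKM in either library.

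The files give no counts. Depth was estimated from low values of genes with a single exon and a single transcript in GENCODE mouse release M21 (the mm10 assembly), which step by the value of 1 fragment. Offsets of 150 to 260 bases for the fragment length were tried in steps of 5. Depths of 34980000 fragments for the SATB1-negative and 26780000 for the SATB1-positive library, with an offset of 210 bases, made 58.9% of 185 and 63.4% of 191 such values whole within 0.05 fragments, against 10% for a depth taken at random. The depth and offset were chosen by a search for this share, so 10% is not the chance level of the chosen fit. In simulated data of the same depths, where every value came from whole fragments, the procedure returned 34780000 and 26540000. Fragments per gene were estimated from the FPKM, these depths and the shortest RefSeq-linked transcript; 20786 symbols, 89.6%, matched a single GENCODE gene. A fold of FPKM was given an exact (Clopper-Pearson) 95% interval on the split of the estimated fragments. These intervals address counting error only and treat each fragment as independent. Fragments amplified by PCR without molecular identifiers are not independent molecules, so the intervals can be too narrow even for counting error. A fragment over 1 kb is worth 0.0286 FPKM in the SATB1-negative and 0.0373 FPKM in the SATB1-positive library.

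With 1 library per group no test of replicates exists and none was run. The ratio log2((SATB1-positive FPKM + 1)/(SATB1-negative FPKM + 1)) understates the difference of genes near or below 1 FPKM, whereas folds printed with an interval are plain ratios of FPKM. A gene met the rule of size when this log2 ratio was at least 1 or at most -1 and its higher library had at least 5 FPKM. The rule, 28 gene lists, the named genes and most of the processing alternatives were set before the data were examined. List members counted as measured at 1 FPKM or more in either library. A member that reached 1 FPKM in 1 library alone can only have a ratio toward that library, so this filter partly sets the counts of signs. Each list's median log2 ratio was given an exact binomial order-statistic 95% interval over its members (none below 6 members). It was also placed as a percentile among medians of 10000 random lists of the same size, drawn from measured genes in the same 20 bins of mean expression. The percentile describes these 2 libraries and is not a test across animals. Several lists share genes: Gzmb, for example, stands in the T and NK cell list and in the mast cell, basophil and eosinophil list.

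Named genes were the sort and reporter genes, the 15 highest and 15 lowest ratios among genes with at least 10 FPKM in the higher library, and up to 4 members per list. The 15 and 15 left out predicted genes, small RNAs, mitochondrial genes and pseudogenes. The list members were the 2 highest and 2 lowest past the rule of size, or the most abundant member where none passed. Other genes are marked as chosen after their values were seen. Some genes that the rule or a small count would name are not reported here. The alternatives were pseudocounts of 0.1 and 5, scaling by the median ratio, by the sum (TPM) and by the upper quartile, other filters on low values, and a 4-fold threshold. Leaving out replicates was not possible.

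The rule was tested on simulated data for this comparison, with Poisson counts for 20088 genes and 200 changed genes. The changed genes had a mean of at least 10 FPKM. The rule counted 100% of 3-fold higher and 100% of 3-fold lower genes, 0% of 1.5-fold genes and 0 of 8046 unchanged genes with at least 5 FPKM. These counts held no spread between sorts, animals or amplifications. The shares therefore show that the rule computes as written and give no rate of false calls in the real libraries. A list of 20 genes 1.5-fold higher stood at the 100th percentile, and 1 of 40 unchanged lists fell outside the central 95%. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1, and plots matplotlib 3.10.9.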

Results

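The transcriptomes of mouse hematopoietic stem cells (HSCs) with and without expression of SATB1, a chromatin-organizing protein of lymphoid cells, were compared by RNA sequencing. The cells carried a Tomato fluorescent reporter of Satb1, and both fractions fell within the LSK gate (lineage marker-negative, Sca-1-positive, Kit-positive bone marrow stem and progenitor cells) and were CD150-positive and Flt3-negative. There were 2 groups, Satb1-Tomato-negative (SATB1-negative) and Satb1-Tomato-positive (SATB1-positive) HSCs, each with 1 library. The question the design poses is how much each gene's expression in SATB1-positive HSCs departs from that in SATB1-negative HSCs. With 1 library per group the differences have no replicate check, so no p-value was computed. A gene was counted as different when log2((SATB1-positive FPKM + 1)/(SATB1-negative FPKM + 1)) was at least 1 or at most -1, with at least 5 FPKM in the higher library. Intervals beside folds are 95% intervals for counting error only and do not cover the spread between animals or sorts. Such intervals can be too narrow, since PCR copies of a molecule count as separate fragments. They start from fragment numbers estimated from the FPKM, the shortest annotated transcript and a depth of about 34980000 fragments for the SATB1-negative and 26780000 for the SATB1-positive library.

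Satb1 itself was higher in the SATB1-positive library, at 8.26 FPKM against 2.37 FPKM in the SATB1-negative library, a 3.48-fold difference (3.02 to 4.02; about 719 and 270 fragments). Its log2 ratio was 1.46, and 0.85 with a pseudocount of 5, which is under the rule of size. The gene (ENSMUSG00000023927.15) lies on the minus strand of chromosome 17 at positions 51736187 to 51833290 of mm10. Of the genes behind the sort, Kit was at 318 FPKM in the SATB1-negative and 286 FPKM in the SATB1-positive library, and Ly6a, which encodes Sca-1, at 64.5 and 73.9 FPKM. Slamf1, which encodes CD150, was at 15.97 and 11.9 FPKM, and Flt3, a cytokine receptor of lymphoid-primed progenitors, at 17.3 and 27.1 FPKM. None of these 4 genes met the rule of size. Cd48, a marker of progenitors downstream of HSCs, was at 47.6 FPKM in the SATB1-negative and 145 FPKM in the SATB1-positive library, 3.05-fold higher (2.85 to 3.26). Cd34 was at 167 and 248 FPKM and Ptprc, which encodes CD45, at 80.5 and 87.1 FPKM. Among lineage marker genes, the T cell receptor component Cd3e was at 2.76 and 15.4 FPKM and the interleukin-7 receptor gene Il7r at 0.727 and 7.64 FPKM. Cd4 was at 2.77 and 4.47 FPKM, Cd8a at 0.326 and 1.07 FPKM and Itgam at 8.14 and 11.4 FPKM. Over the 13 measured sort and reporter genes, 4 passed the rule of size as higher (Satb1, Cd48, Cd3e and Il7r) and 0 as lower. Their median log2 ratio was 0.57 (0.11 to 1.59), above all 10000 random lists. Xist was at 35.2 and 36.4 FPKM, and it was the single measured member of the list of X-inactivation and Y-chromosome genes, whose log2 ratio of 0.05 stood at the 56.5th percentile of random lists.

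The 2 libraries were alike for most genes. Of 9308 genes with at least 5 FPKM in either library, 98.0% did not pass the rule of size, and the median absolute log2 ratio was 0.16. The rule counted 122 genes as higher and 64 as lower in the SATB1-positive library. Small RNA genes made up 19 of the 122 and 25 of the 64, and many of them were listed at 0 in one library; unrelated small RNA genes shared identical values, as Scarna8 and Snora34, chosen after their values were seen, did at 20.1 FPKM in the SATB1-positive library. Without small RNA genes, 103 genes were higher and 39 lower. The Pearson correlation of log2(FPKM + 1) across the 23210 genes was 0.991; genes are not independent replicates.

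**Figure D1:**
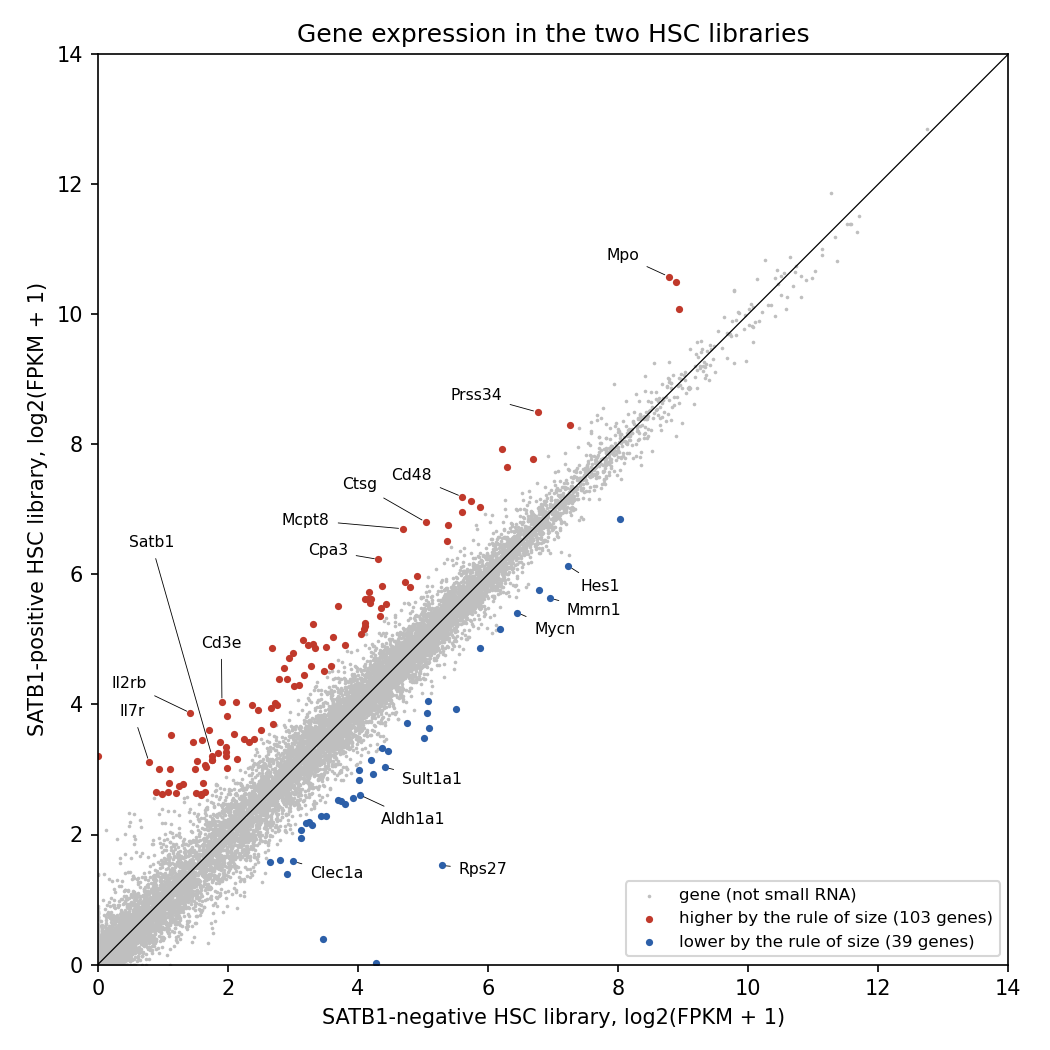
Expression of each gene other than small RNA genes, as log2(FPKM + 1), in the SATB1-negative library (x axis) and the SATB1-positive library (y axis); each point is a gene and the line marks equal values. The 103 genes higher in the SATB1-positive library by the rule of size (red) include lymphocyte, basophil and granule genes, and the 39 lower genes (blue) include Mmrn1, Hes1 and Mycn.

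Several genes of T and natural killer (NK) cells were among the higher genes. Of 22 measured members of the list of T and NK cell genes, 10 passed the rule of size as higher (5 with a pseudocount of 5), 0 passed as lower, and 21 had a log2 ratio above 0. Cd8a, Cd5, Zap70, Trat1, Bcl11b, Klrd1, Ncr1, Gzma and Gzmb reached 1 FPKM in the SATB1-positive library alone, so the filter fixed their sign. The list's median log2 ratio was 1.14 (interval of the median over members 0.85 to 1.70), above all 10000 random lists matched on expression. Il2rb, the shared receptor subunit for interleukin-2 and interleukin-15, was at 1.69 FPKM in the SATB1-negative and 13.6 FPKM in the SATB1-positive library, 8.07-fold higher (7.02 to 9.30). Cd3e was 5.59-fold higher (4.56 to 6.85), and Cd3g, at 2.95 and 13.2 FPKM, 4.48-fold higher (3.49 to 5.76). Further lymphocyte genes stood among the 15 highest ratios of genes with at least 10 FPKM. The chemokine receptor gene Cxcr6 was 8.86-fold higher (6.91 to 11.6) and Ms4a4b 5.22-fold (4.84 to 5.63). The T and NK cell chemokine gene Ccl5 was 4.13-fold higher (3.30 to 5.24) and Gimap3, a lymphocyte GTPase gene, 3.82-fold (3.45 to 4.26). The cystatin gene Cst7, also among these 15 but not counted as a lymphocyte gene here, was 3.72-fold higher (3.28 to 4.25). B cell genes did not show the rise of the T and NK cell genes. Only 2 of 17 B cell genes were measured, and their median log2 ratio was -0.02, at the 42.5th percentile; Cd79b was at 34.3 and 33.9 FPKM.

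Early lymphoid genes had ratios on both sides of 0. Of 25 measured members, 18 had a ratio above 0, 4 passed the rule of size as higher (2 with a pseudocount of 5) and 1 passed as lower. The median log2 ratio was 0.23 (0.03 to 0.89), at the 99.97th percentile. Il7r, needed for lymphocyte development, was 10.5-fold higher (8.35 to 13.3) and Satb1, a member of the list on whose reporter the cells were sorted, 3.48-fold. Igj, chosen after its values were seen, also passed as higher. Hes1, a transcriptional repressor downstream of Notch, was at 150 FPKM in the SATB1-negative and 68.9 FPKM in the SATB1-positive library, 2.17-fold lower (2.07 to 2.28). Dntt, the DNA polymerase of early lymphocytes, was at 1.20 and 3.08 FPKM; this gene was chosen after its values were seen, and it is under the 5 FPKM minimum. Some of the higher T and NK cell genes, such as Cd3e and Cd3g, are expressed by mature T cells, as are Il7r and Satb1. Nkg7, chosen after its values were seen, also passed the rule but was already at 152 FPKM in the SATB1-negative library. Such a gene does not mark mature lymphocytes alone.

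Mast cell, basophil and eosinophil genes had a median log2 ratio of 1.58 (0.57 to 1.96), above all 10000 random lists. Of 12 measured members, 7 passed the rule of size as higher and 0 as lower. The basophil protease gene Mcpt8 was at 24.8 FPKM in the SATB1-negative and 103 FPKM in the SATB1-positive library, 4.16-fold higher (3.77 to 4.59). Cpa3, the mast cell carboxypeptidase, was 3.92-fold higher (3.62 to 4.24), and Gzmb, which NK and cytotoxic T cells also express, 7.64-fold (5.40 to 10.9) at 0.926 and 7.07 FPKM.

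Of 17 measured neutrophil and granule genes, 4 passed the rule of size as higher and 0 as lower, with a median log2 ratio of 0.09 (-0.25 to 0.79) at the 94.2th percentile, or -0.0058 over members with at least 5 FPKM. Mpo, myeloperoxidase of primary granules, was at 437 FPKM in the SATB1-negative and 1528 FPKM in the SATB1-positive library, 3.49-fold higher (3.45 to 3.53), and the cathepsin gene Ctsg was 3.47-fold higher (3.21 to 3.75). The other two were Elane, at 490 and 1081 FPKM, and Ms4a3, at 52.5 and 139 FPKM. Both were chosen after their values were seen. Of the list's members, 9 had a ratio above 0 and 8 below. The members named next were chosen after their values were seen. The 8 included Camp (log2 ratio -0.59), Ltf (-0.49), S100a8 (-0.45) and Ngp (-0.25), while Prtn3 (0.79) and S100a9 (0.12) were among the 9. Ngp was at 236 FPKM in the SATB1-negative and 198 FPKM in the SATB1-positive library, and S100a8 at 117 and 85.5 FPKM. The source of these transcripts in either library was not tested. Among 12 measured myeloid regulator genes, 2 passed the rule of size as higher (0 with a pseudocount of 5), and the median log2 ratio was 0.27 (-0.10 to 0.99) at the 99.9th percentile. Cebpa, a transcription factor of granulocyte and monocyte commitment, was 3.31-fold higher (2.78 to 3.94) and Gfi1 2.68-fold (2.39 to 3.002). Of 20 measured monocyte, macrophage and dendritic cell genes, 17 had a ratio above 0 and 0 met the rule of size, with a median of 0.45 (0.08 to 0.69), above all 10000 random lists; Lyz2, the most abundant, was at 395 and 416 FPKM. The chemokine gene Ccl9 (4.60-fold, 4.07 to 5.22) and Rab44 (3.89-fold, 3.62 to 4.19) were also among the 15 highest ratios.

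Of 33 measured HSC genes, 32 had a log2 ratio below 0, 4 passed the rule of size as lower (1 with a pseudocount of 5, Sult1a1) and 0 as higher. The median log2 ratio was -0.65 (-0.78 to -0.48), a median fold of 0.637 and below all 10000 random lists. The C-type lectin gene Clec1a was at 7.04 FPKM in the SATB1-negative and 2.003 FPKM in the SATB1-positive library, 3.52-fold lower (2.96 to 4.21). The sulfotransferase gene Sult1a1 was 2.83-fold lower (2.45 to 3.31). The other two were Fhl1 and Tcf15, chosen after their values were seen. Members below the rule of size, chosen after their values were seen, included Esam at 68.5 and 34.2 FPKM, Mecom at 49.4 and 31.1 FPKM and Vwf at 12.3 and 6.79 FPKM. Hox genes and cofactors, several of which support stem cell self-renewal, were below 0 in 12 of 13 measured members, with 0 past the rule of size. Their median was -0.64 (-0.88 to -0.09), below all 10000 random lists, and Meis1, the most abundant member, was at 225 and 178 FPKM.

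Other genes among the 15 lowest ratios included Aldh1a1, a retinaldehyde dehydrogenase (3.01-fold lower, 2.46 to 3.72), the luteinizing hormone receptor gene Lhcgr (2.90-fold, 2.69 to 3.13) and Mmrn1, multimerin of platelets and endothelium (2.54-fold, 2.46 to 2.61; 123 and 48.6 FPKM). The amino acid transporter gene Slc6a15 was 2.67-fold lower (2.43 to 2.92), Art4 2.37-fold (2.19 to 2.56), the tetraspanin gene Cd151 2.52-fold (2.13 to 3.005), Npdc1 2.46-fold (2.11 to 2.89) and Smagp 2.67-fold (1.84 to 3.89). Several broadly expressed genes were also on this list. Rab5c was 3.15-fold lower (2.89 to 3.43), Npm3, which has an exon overlapping another gene, 3.10-fold (2.64 to 3.67), Max 2.88-fold (2.62 to 3.18) and Eif4a2, which also overlaps another gene, 2.27-fold (2.203 to 2.34). Rps27, a ribosomal protein gene on chromosome 3 at 90212522 to 90213651, was also among them, at 38.2 FPKM in the SATB1-negative and 1.88 FPKM in the SATB1-positive library, far under Rpl13, which had the highest mean FPKM of the listed ribosomal protein genes, at 3252 and 2465 FPKM. About 7 fragments lie behind the lower Rps27 value, and 25% of its 50-base words occur in transcripts of other genes. U05342, listed under this symbol and without a transcript match, was at 10.1 and 0.318 FPKM. Zfp91, a zinc finger gene whose exons overlap another gene, was among the highest ratios, at 6.65 and 25.1 FPKM.

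Platelet, erythroid and stromal lists had mixed members. Of 26 measured megakaryocyte and platelet genes, 1 passed the rule of size as higher and 0 as lower, and the median log2 ratio of -0.04 (-0.37 to 0.18) stood at the 29.0th percentile. That gene was Ppbp, a platelet chemokine, at 2.27 and 11.2 FPKM (4.96-fold higher, 3.81 to 6.59), while Itga2b, chosen after its values were seen, was at 62.8 and 67.3 FPKM. Of 17 measured erythroid genes, 1 passed the rule of size as higher (0 with a pseudocount of 5), the globin gene Hbb-b1 at 1.15 and 7.01 FPKM; its near-identical copy Hbb-b2, chosen after its values were seen, was at 11.3 and 7.28 FPKM, so the split of reads between them is uncertain. The erythroid median was 0.16 (-0.13 to 0.41), at the 98.6th percentile. Of 10 measured endothelial and stromal genes, 4 passed the rule of size as higher, of which Col1a1 alone passed with a pseudocount of 5. Col1a1, type I collagen, was at 16.8 and 48.3 FPKM (2.87-fold, 2.76 to 2.99) and Pdgfrb at 3.25 and 10.6 FPKM (3.28-fold, 2.98 to 3.61). The other two were Col1a2 and Sparc, chosen after their values were seen. The median of this list was 0.28 (-0.42 to 1.45), at the 99.6th percentile, and became -0.0066 when members below 1 FPKM were included.

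No listed cell cycle phase gene passed the rule of size. All 28 measured G2 and M phase genes had a ratio above 0. Their median log2 ratio was 0.48 (0.42 to 0.57), a median fold of 1.39 and above all 10000 random lists. Ube2c, a mitotic ubiquitin-conjugating enzyme, was at 145 and 207 FPKM, and the proliferation marker Mki67, chosen after its values were seen, at 46.5 and 81.4 FPKM. All 26 S phase genes also had a ratio above 0, with a median of 0.16 (0.10 to 0.27) at the 99.9th percentile. Their ratios ran from 0.0047 for Dut to 0.97 for Pola1, genes chosen after their values were seen; Mcm6 was at 390 and 406 FPKM. The 16 measured cell cycle inhibitor genes had a median of 0.07 (-0.20 to 0.32) at the 86.6th percentile with 0 past the rule; Btg2 was at 85.7 and 126 FPKM. In the list of multipotent progenitor and cell cycle entry genes, 12 were measured, with Cd48 higher, Mycn 2.08-fold lower (1.99 to 2.18; 86.6 and 41.5 FPKM) and Ccnd1, cyclin D1, 2.33-fold lower (2.06 to 2.65). Of these 3, Cd48 alone passed the rule of size with a pseudocount of 5. Its median was -0.18 (-0.60 to 0.57), at the 0.91th percentile.

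No interferon response gene passed the rule of size. Of 30 measured members, 25 had a ratio below 0 and 5 above, with a median of -0.28 (-0.37 to -0.13), below all 10000 random lists; Irf1, the most abundant and one of the 5, was at 75.3 and 82.3 FPKM. Notch signaling genes had a median of -0.29 (-0.48 to 0.06) at the 0.07th percentile over 15 measured members, of which Hes1 alone met the rule. Cytosolic ribosomal protein genes had a median of -0.16 (-0.21 to -0.07), at the 0.01th percentile, with 35 of 48 below 0 and 0 past the rule. Rps27, which passed the rule as lower, is not a member of this list. Cytokine and chemokine receptor genes had a median of 0.15 (-0.12 to 0.36) at the 99.6th percentile over 30 members, of which Il7r alone met the rule.

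The remaining lists lay near 0. Immediate early and dissociation stress genes had a median of 0.09 (-0.08 to 0.35) at the 98.7th percentile, and 3 of 32 members passed the rule of size as higher. These were the heat shock genes Hspa1b (2.76-fold, 2.55 to 2.98) and Hspa1a (2.71-fold, 2.45 to 3.01), which are near-identical copies, and Tnfaip3, chosen after its values were seen. With a pseudocount of 5 the Hspa1a log2 ratio was 0.93, under the rule. Chromatin and epigenetic regulator genes had a median of 0.08 (-0.0043 to 0.16) at the 96.5th percentile, and Satb1 was the 1 of 35 members past the rule (0 with a pseudocount of 5). Oxidative phosphorylation genes had a median of -0.05 (-0.12 to 0.02) at the 12.5th percentile, and Atp5b was at 583 and 672 FPKM. Glycolysis genes had a median of 0.10 (-0.05 to 0.22) at the 95.1th percentile, with Gapdh at 441 and 611 FPKM. MHC class I and II genes had a median of -0.08 (-0.27 to -0.01) at the 11.1th percentile, with B2m at 2644 and 1801 FPKM. Housekeeping genes had a median of 0.02 (-0.11 to 0.20) at the 75.2th percentile, which turned to -0.0016 with scaling by the upper quartile, with Eef1a1 at 6849 and 7357 FPKM. None of the measured members of these last 4 lists met the rule. Rn45s, named for the 45S ribosomal RNA precursor and chosen after its values were seen, was at 472 FPKM in the SATB1-negative and 1437 FPKM in the SATB1-positive library. Its value does not tell precursor from mature ribosomal RNA left in a library, and the source of the difference was not tested.

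**Figure D2:**
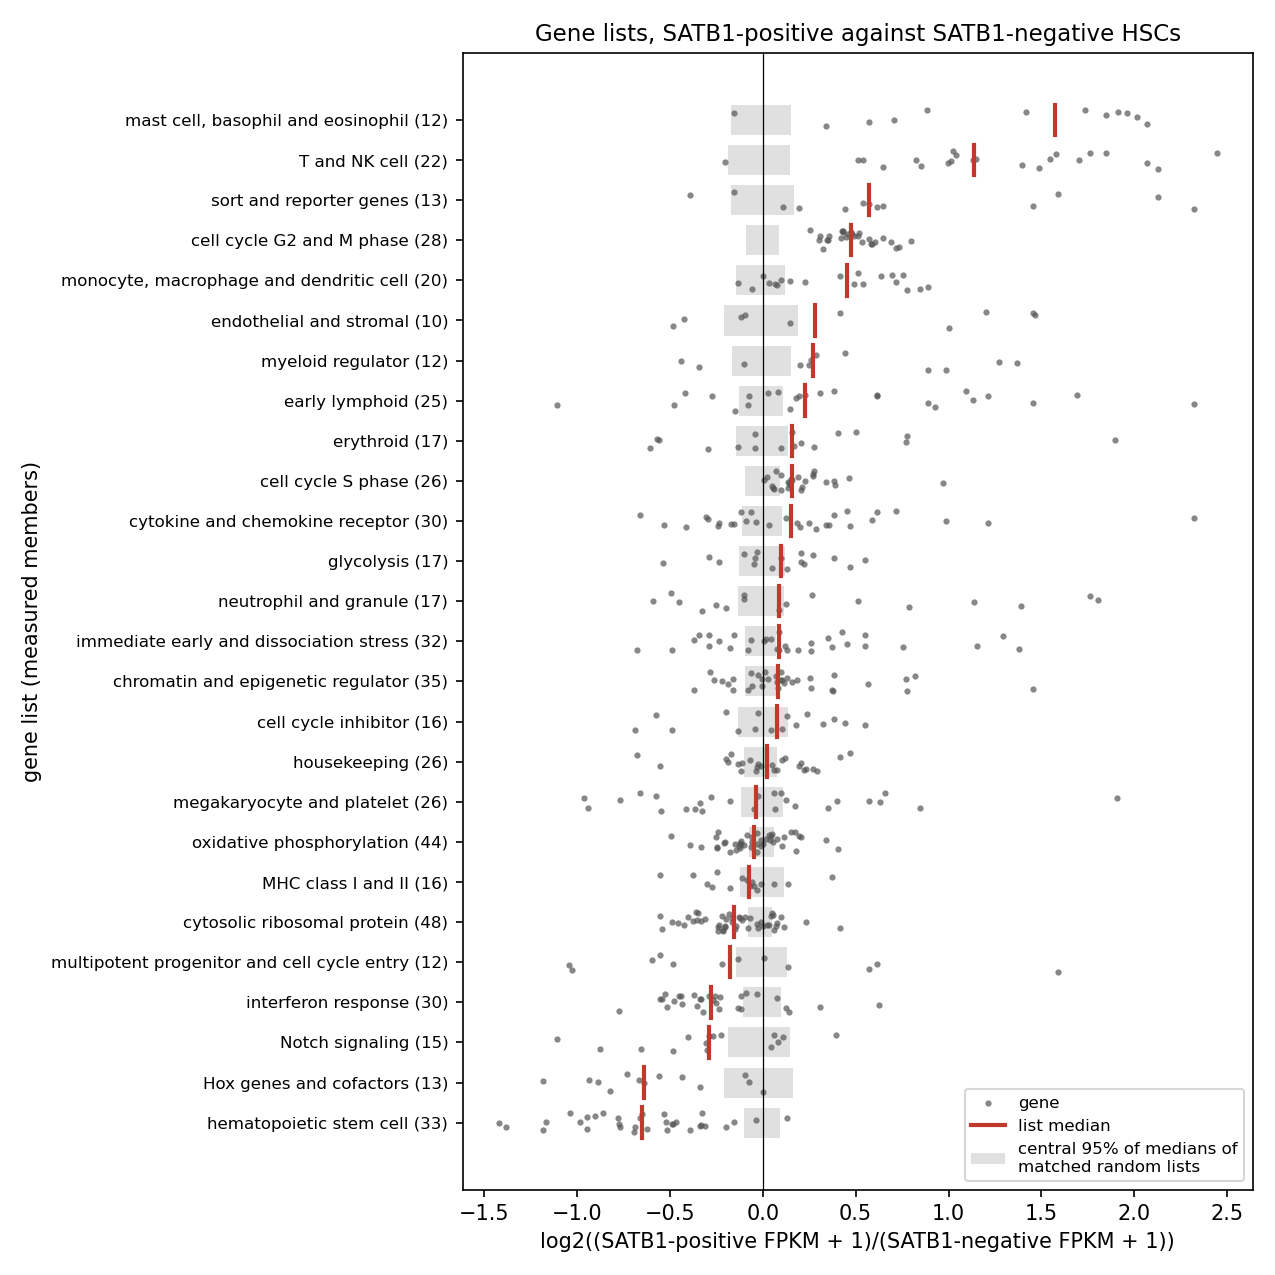
Log2((SATB1-positive FPKM + 1)/(SATB1-negative FPKM + 1)) on the x axis for each measured member (points) of the gene lists with at least 6 measured members (rows, number of members in parentheses), with the list median (red line) and the central 95% of medians of 10000 expression-matched random lists (grey bar). Medians run from -0.65 for HSC genes to 1.58 for mast cell, basophil and eosinophil genes.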

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

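The count of 122 higher and 64 lower genes depended on the pseudocount and filter. It was 68 and 36 with a pseudocount of 5, 58 and 30 with at least 20 FPKM in the higher library, and 24 and 25 at 4-fold. After scaling to TPM, which doubles the values against a fixed pseudocount and minimum, it was 174 and 100. Without small RNA genes, an alternative chosen after seeing the data, the lower count was 39. Calls per list with a pseudocount of 5 were also counted after seeing the data; the 7 mast cell, basophil and eosinophil and 4 neutrophil and granule counts stayed at 7 and 4. Before a pseudocount, scaling by the median ratio shifts log2 ratios by 0.00031, TPM by 0.003 and the upper quartile by -0.023. With the pseudocount of 1, TPM moved Il7r from 2.32 to 2.74 and Satb1 from 1.46 to 1.61. The upper quartile turned the housekeeping median from 0.02 to -0.0016, and no other list median or named gene changed sign under a scaling. The Satb1 log2 ratio was 1.76 with a pseudocount of 0.1 and 0.85 with 5, and the median of T and NK cell genes 1.90 and 0.68. With no filter on low values the endothelial and stromal median turned from 0.28 to -0.0066, the X-inactivation and Y-chromosome median was -0.0196 and the B cell median 0.05; these lists gain members below 1 FPKM. With at least 5 FPKM the neutrophil and granule median was -0.0058. Of 182 recomputed medians of the 26 lists with an interval, 179 stayed within it. Of 330 values for the 66 named genes with a counting interval other than Satb1, 63 moved beyond it, 54 of them with another pseudocount. No symbol was repeated, so keeping the highest row of a symbol could not be run. No paired analysis was possible because each group has 1 library. Counting intervals stayed wide for some genes above 5 FPKM, such as Smagp (1.84 to 3.89-fold lower) and Rps27 (9.36 to 49.7-fold lower), and no replicate shows the spread between sorts.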

Other observations

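The gene families and single genes named here, the test of the Satb1 fold against T cell genes, the test on genes shared by stem and progenitor cells and the other filters on the second T and NK cell list were chosen after their results were seen. All 6 measured killer cell lectin-like receptor genes, of 35 in the family, had a log2 ratio above 0, with 0 past the rule of size. Klrb1b, Klrc1, Klrd1 and Klrk1 reached 1 FPKM in the SATB1-positive library alone, so the filter fixed their sign. Klrb1c and Klrb1f alone could have gone either way. Of the 6, 4 also stand in the T and NK cell lists. Klrk1 was at 0.477 FPKM in the SATB1-negative and 2.94 FPKM in the SATB1-positive library. Of 13 measured chemokine ligand genes, 5 passed the rule of size as higher and 0 as lower: Ccl5, Ccl9, Xcl1, Ccl3 and Cxcl2. Ccl3 was at 16.9 and 52.0 FPKM, while Cx3cl1, under the 5 FPKM minimum, was at 4.52 and 1.97 FPKM. Of 8 Gimap genes, which encode lymphocyte GTPases, Gimap3, Gimap4 and Gimap7 passed the rule as higher, whereas Gimap6, the most abundant, was at 222 and 166 FPKM. Their median was 0.35 (-0.43 to 1.79).

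Among 15 genes of the nucleolar small RNA machinery, Fbl, the fibrillarin methyltransferase (77.7 and 200 FPKM), and Gar1 (29.1 and 61.7 FPKM) passed the rule of size as higher and Npm3 as lower; the median was 0.19 (-0.11 to 0.36). Of 10 measured interleukin genes, 1 passed the rule as higher, Il6 at 2.15 and 7.42 FPKM, and the median was -0.19 (-0.66 to 0.30). Type I collagen chains Col1a1 and Col1a2 passed the rule as higher, while the type IV chains Col4a1 (15.6 and 12.1 FPKM) and Col4a2 (14.4 and 10.6 FPKM) did not, and the median of 8 collagen chain genes was 0.08. Histone genes had a median of 0.09 over 23 members.

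Of 22 T and NK cell genes, 10 passed the rule of size as higher, as Satb1 did, and a candidate explanation is a small number of mature T or NK cells among the sorted SATB1-positive cells, although the lineage gate of the sort should remove CD3-positive cells. A second list of 36 measured T and NK genes left out the first list and the genes seen to differ. Its median log2 ratio was 0.61 (0.09 to 0.99), which passed the bound of 0.5 set in advance for this explanation. Of the 36, 14 reached 1 FPKM in the SATB1-positive library only and 0 in the SATB1-negative library only. The median was 0.37 (0.16 to 0.72) over all 49 genes without a filter, under that bound. Over the 22 genes with at least 1 FPKM in the SATB1-negative library it was 0.07 (-0.19 to 0.44). That value lies under the bound set in advance against the explanation, but this filter leaves out genes higher in the SATB1-positive library. Of these 22 the most abundant, Rgs1, was at 628 FPKM in the SATB1-negative and 705 FPKM in the SATB1-positive library. Dusp2, at 231 FPKM, and Icam2, at 66.2 FPKM, were also abundant in the SATB1-negative library. A small number of T or NK cells would hardly move genes at such levels, so the 0.07 cannot be counted against the explanation. The result depends on the filter, so this test does not decide. The Satb1 fold of 3.48 lay inside the range of 2.11 to 8.54 over 7 T cell receptor and signalling genes, but the range is wide and a sort on the Satb1 reporter predicts a higher Satb1 value as well, so whether such cells carried Satb1 transcript cannot be told apart from the sort. Lymphoid genes transcribed in SATB1-positive HSCs are another explanation, which remains open and was not tested. Non-lymphoid genes rose too: 7 of 12 mast cell, basophil and eosinophil genes and 4 of 10 endothelial and stromal genes passed the rule as higher. The source of those differences was not tested.

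The median of the HSC list lay below all random lists, although 4 of its 33 members passed the rule of size. Dilution of all stem and progenitor RNA by mature cells would lower genes shared by stem and progenitor cells about as much as the HSC genes. A list of 31 such genes had a median log2 ratio of -0.055 (-0.15 to 0.11), and -0.02 (-0.13 to 0.12) without the 3 genes it shares with the HSC list, against -0.65 (-0.78 to -0.48) for the HSC list, which argues against dilution as the whole cause. Some of the list, such as Ptprc, is also expressed by mature blood cells, which would not dilute it, and this weakens the test. Of the 31 genes, 13 had a ratio above 0 and 18 below. Tal1 (-0.75) and Myct1 (-0.71) fell about as far as the HSC list median. A different make-up of the gated cells, with more progenitors that express Cd48 and Mpo, and a difference within HSCs by SATB1 both stay open, as hypotheses from 1 library each.

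Broadly expressed genes such as Rps27, Rab5c, Max, Eif4a2 and Zfp91 also passed the rule of size. Reads shared with near-identical copies could move such genes between libraries. Of 129 genes past the rule outside small RNA genes with a transcript model, 10.9% (Clopper-Pearson interval 6.06 to 17.5%) had at least 10% of their 50-base words in other genes, against 9.31% of 247 expression-matched genes; 26.4% (18.99 to 34.8%) had an exon overlapping another gene, against 36.0%. Both intervals lie under 50%, so neither accounts for most of the differences. For single genes it stays open: 25% of the words of Rps27 and 22.6% of those of Npm3 occur elsewhere, as do 10.6% of those of Eif4a2 and 8.48% of those of Zfp91, against 0.028% for Max and 0% for Rab5c.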
